A study of Drosophila melanogaster with 33 samples.

How the data were processed

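ChIP-seq samples of S2-DRSC cells and of S2 cells expressing HA-tagged AbdA were compared through their deposited peak lists. The labels name the same list for both replicates of an antibody in a line, and how the replicates were combined is not given in the sources used here. The HA control sample of S2 cells and the 6 input samples entered no comparison because no peak list of theirs was used here. The deposited score of each peak is a positive number of unstated unit, per the labels and the values themselves, and was never compared between lists. Per the labels, the authors used BWA 0.7.12 and MACS2 on build dm3, and the settings are not given in the sources used here. Per the peak names in the files, the Ser2P lists held broad peaks. The build was checked on the chromosome names and the largest peak ends, for example 27898841 on 3R, which differ from Release 6 of the fly genome, where 3R is 32079331 bp long. The annotation and genome at hand were Release 6, so no gene, promoter or motif was assigned and coordinates of the builds were never mixed. Starts are printed 1-based.

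Samples were grouped by line and antibody from the labels. Peaks were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and tests were run with scipy 1.17.1. An overlap of 1 bp or more counted as shared. HA-AbdA peaks were compared with each factor list by 1000 circular shifts of the HA-AbdA peaks along each chromosome, whose length was taken as the largest end in any list (one-sided, and 200 shifts for the alternatives of factor pairs). For each factor, the lists of the 2 lines were merged into regions with peaks in both lines (kept), in S2-AbdA cells only (gained) or in S2 cells only (lost). Shares of regions with an HA-AbdA peak were compared by the two-sided Fisher exact test and by 10000 circular shifts of the HA-AbdA label along the genome order of the regions (two-sided, drawn with replacement). Benjamini-Hochberg adjustment covered 12 factor overlaps, 12 comparisons of gained or lost regions and 60 ordered factor pairs, at a threshold of 0.05. Stratified odds ratios used the Cochran-Mantel-Haenszel estimate over 5 quintiles of the peak's own score, with the label permuted within quintiles. For peaks new in S2-AbdA cells at kept Rpb3 regions, the odds ratio with HA-AbdA or M1BP was divided by that of the same factor in S2 cells, with a 95% interval from 1000 bootstrap resamples of blocks of 50 regions in genome order. Other intervals are exact Clopper-Pearson 95% intervals. No read depth is known, so no floor for absent peaks was computed.

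The groups, tests, thresholds and the rule for named peaks were fixed before the data were examined. The rule named the 10 HA-AbdA peaks with the highest score, the 5 gained and 5 lost peaks per factor with the highest score in their own list, and the 5 clusters of HA-AbdA peaks (gaps of up to 10 kb) with most peaks. Further examples from the same ranking on the arms, and single peaks chosen from these sets for the text, were picked after their values were seen. Alternatives fixed in advance were an overlap of at least 50% of the shorter peak, peak centres within 250 bp, the higher-scoring 50% of each list, lists of equal length, gained and lost counts among strong peaks, score quintiles, and regions on or off Rpb3 peaks. The restriction to the arms 2L, 2R, 3L, 3R, X and 4 was fixed in advance for the HA-AbdA list and its overlaps and was added for the other comparisons after the data were examined. Also added then was the removal of recurrent sites, which are arm regions with a peak in at least 6 of the other lists rich in unplaced sequence. Those rich lists are the 9 with more than 20% of peaks outside the arms.

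The overlap code was checked against bedtools 2.31.1 in 39 counts, of which 0 differed. The tests were tested on simulated data drawn from these lists. Circular shifts of peaks made 1 call in 20 runs with no simulated overlap and 20 calls in 20 runs when 0.02 of the 10352 peaks were placed on S2 M1BP peaks. Label shifts made 2 calls in 50 runs with no simulated difference and 45 calls in 50 runs with a share higher by 0.05. The simulated labels and peak positions were drawn independently of their neighbours, so these rates do not cover the clustering of the real HA-AbdA peaks. A simulated odds ratio of 2 was recovered as 2.03 by the stratified estimate.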

Results

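The series compared S2-DRSC cells, a Drosophila melanogaster line of embryonic origin, with S2 cells that stably express an HA-tagged form of AbdA, the Hox protein Abdominal-A, which sets the identity of abdominal segments. Both lines received 10 µM copper sulphate for 24 h. Chromatin was immunoprecipitated and sequenced (ChIP-seq) with antibodies against the HA tag and against 6 factors. Rpb3 is a subunit of RNA polymerase II, taken in the labels as a mark of poised polymerase, and Pol II Ser2P is the phosphorylated, elongating form. M1BP (Motif 1 binding protein) and GAF (GAGA factor) bind promoters. dRing belongs to the Polycomb complex PRC1, and E(z) is the histone methyltransferase of the Polycomb complex PRC2. The 33 samples formed 18 groups. Each factor had 2 replicates in each line, the HA tag had 2 replicates in S2-AbdA cells and 1 control sample in S2 cells, and 6 samples were input chromatin. The labels do not say whether replicates came from separate cultures.

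The authors gave 1 peak list per antibody and line, 13 lists in all, on the fly genome build dm3. No replicate therefore entered any comparison, and every p-value describes these lists and not replicate cultures. The lists hold no read counts, so the depth of each sample is unknown. The score of each peak is the authors' and its unit is not given, so scores were used only to rank and filter peaks within a list. The HA control sample of S2 cells had no list used here, so the background of the HA antibody is not known. Exact Clopper-Pearson 95% intervals cover counting error only. Peaks are named by dm3 position because no dm3 gene annotation was used here.

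The HA-AbdA list held 10352 peaks, with a median width of 836 bp and a covered length of 12.1 Mb. Rpb3 had 9370 peaks in S2 cells and 8896 in S2-AbdA cells, and Pol II Ser2P had 4309 and 6377. M1BP had 7157 and 6639 peaks, and GAF had 7083 and 9530. dRing had 4891 and 6615 peaks, and E(z) had 6619 and 6558. The lists differed in how many of their peaks lay outside the 6 chromosome arms (2L, 2R, 3L, 3R, X and 4), in heterochromatic or unplaced sequence. Only 0.386% of HA-AbdA peaks (95% interval 0.276 to 0.526%) lay there, and the Rpb3 lists held 0.598% and 0.629%. In the Ser2P lists the share was 61.2% in S2 cells and 43.1% in S2-AbdA cells, and in the M1BP, dRing and E(z) lists it ran from 20.1% to 39.6%. The GAF lists differed between the lines, with 23.7% (95% interval 22.7 to 24.7%) in S2 cells and 0.609% (95% interval 0.462 to 0.786%) in S2-AbdA cells. The labels gave the GAF sample of S2-AbdA cells the same input code as HA-AbdA, code C, whereas the other factors of that line had code D and all 6 factors of S2 cells had code B. Line and input code could therefore not be separated for any of the 6 factors.

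**Figure D1:**
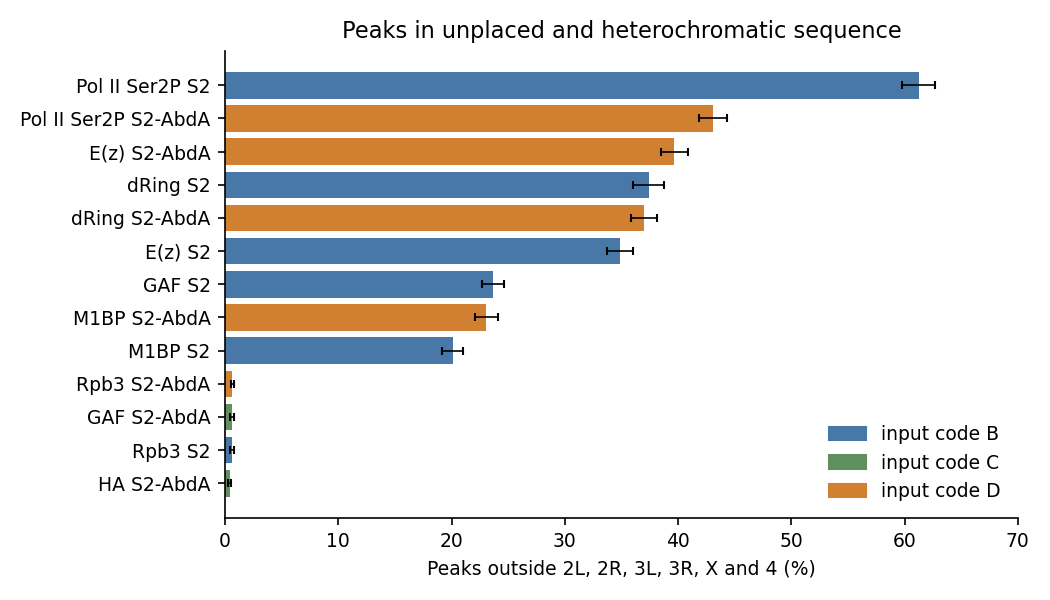
Share of the peaks of each list (percent, bars with exact 95% binomial intervals) that lay outside the arms 2L, 2R, 3L, 3R, X and 4, for the 13 lists, coloured by input code. The HA-AbdA list, both Rpb3 lists and the GAF list of S2-AbdA cells lay at or under 0.629%, and the other lists lay between 20.1% and 61.2%.

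The first question of the design was where AbdA binds. HA-AbdA peaks lay on all major arms, with 2429 on 3R, 2407 on 3L, 1967 on 2L, 1964 on 2R, 1506 on X and 39 on chromosome 4. The highest-scoring peak lay at 3R 7908621 to 7910096 (score 289), on Rpb3, GAF and E(z) peaks of both lines and on a dRing peak in S2 cells alone. The next lay at 2L 13569430 to 13574103 (score 271) and at 3L 21476781 to 21477649 (score 269), and both also overlapped M1BP, GAF and E(z) peaks of both lines and a dRing peak in S2 cells alone. A peak at 3L 21353973 to 21354832 (score 266) overlapped GAF and E(z) in both lines. The peak at 3R 10569912 to 10571115 (score 263) overlapped no factor peak in S2 cells but Rpb3, GAF and E(z) peaks in S2-AbdA cells. The peaks at 2R 8499578 to 8501376 (score 259) and 2L 12586692 to 12587998 (score 256) overlapped Rpb3 and E(z) in both lines. The peak at 4 521818 to 524757 (score 251) overlapped Rpb3, dRing and E(z) in both lines and GAF in S2 cells alone. Of the remaining pair of the 10 highest, 3L 14189243 to 14190992 (score 243) overlapped only GAF in S2-AbdA cells, and 3L 7624413 to 7625778 (score 238) overlapped no factor.

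HA-AbdA peaks formed 2628 clusters when peaks up to 10 kb apart were joined. The cluster with most peaks spanned 170 kb at 3R 16879196 to 17049639, where 53 HA-AbdA peaks covered 39.7% of the sequence. That cluster held 42 Rpb3 and 15 E(z) peaks in S2 cells, and its GAF peaks numbered 22 in S2 cells and 34 in S2-AbdA cells. At 2L 12416065 to 12546948, 42 peaks covered 42.3% of 131 kb, with 15 GAF peaks in S2 cells and 36 in S2-AbdA cells. Clusters of 40 peaks each lay at 2L 10382954 to 10529848, 2R 9797752 to 9925669 and 3L 17517580 to 17664993, spanning 147 kb, 128 kb and 147 kb. The cluster on 2L near 10382954 was the one of the 5 with more M1BP peaks (24) than GAF peaks (5) in S2 cells.

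The next comparison asked which chromatin AbdA bound, described by the factor peaks of S2 cells, without AbdA, and of S2-AbdA cells. Rpb3 was the most frequent partner: 47.4% of HA-AbdA peaks (95% interval 46.4 to 48.3%) overlapped an Rpb3 peak of S2 cells, against a mean of 13.0% when HA-AbdA peaks were shifted along their chromosomes. M1BP peaks of S2 cells lay at 33.0% of HA-AbdA peaks (shifted mean 7.97%), GAF at 28.1% (8.59%), E(z) at 23.7% (5.76%), dRing at 15.6% (4.17%) and Ser2P at 11.5% (4.19%). In the lists of S2-AbdA cells the overlap was 45.6% for Rpb3, 42.4% for GAF, 29.4% for M1BP, 26.2% for Ser2P, 20.7% for E(z) and 17.8% for dRing. Seen from the factors, 63.5% of S2 Rpb3 peaks overlapped HA-AbdA, as did 49.7% of M1BP, 42.9% of GAF, 41.1% of E(z), 35.4% of dRing and 22.9% of Ser2P peaks of S2 cells. On the arms alone these shares lay closer together, at 63.7% for Rpb3, 61.9% for M1BP, 56.1% for GAF, 62.9% for E(z), 56.3% for dRing and 58.6% for Ser2P.

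All 12 overlaps were larger than in any of 1000 circular shifts, which keep peak widths and spacing (one-sided permutation p = 0.001 and adjusted p = 0.001 for each, the smallest these shifts can give). The observed HA-AbdA shares were 2.62 to 4.16 times the shifted means. In the S2 lists this ratio was 4.14 for M1BP, 4.12 for E(z), 3.73 for dRing, 3.64 for Rpb3, 3.28 for GAF and 2.74 for Ser2P. Rpb3, which had the longest S2 list of the 6 factors, thus led by share and not by this ratio. With the higher-scoring 50% of each list, the overlap with S2 Ser2P peaks was 1.60% and no longer passed the test. Of the S2 Ser2P peaks, 2639 of 4309 lay outside the arms, with a median score of 17.1 against 4.27 on the arms. The higher-scoring 50% of that list thus lay mostly in sequence where HA-AbdA had few peaks. Within Rpb3 peaks of S2 cells, HA-AbdA lay at 80.1% of those that also had an E(z) peak and at 58.4% of those that had none (odds ratio 2.86), and the odds ratio was 2.51 for dRing, 2.02 for M1BP, 1.83 for GAF and 1.46 for Ser2P. For Ser2P within the Rpb3 peaks of S2-AbdA cells it was 1.07 and did not pass the two-sided Fisher exact test.

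**Figure D2:**
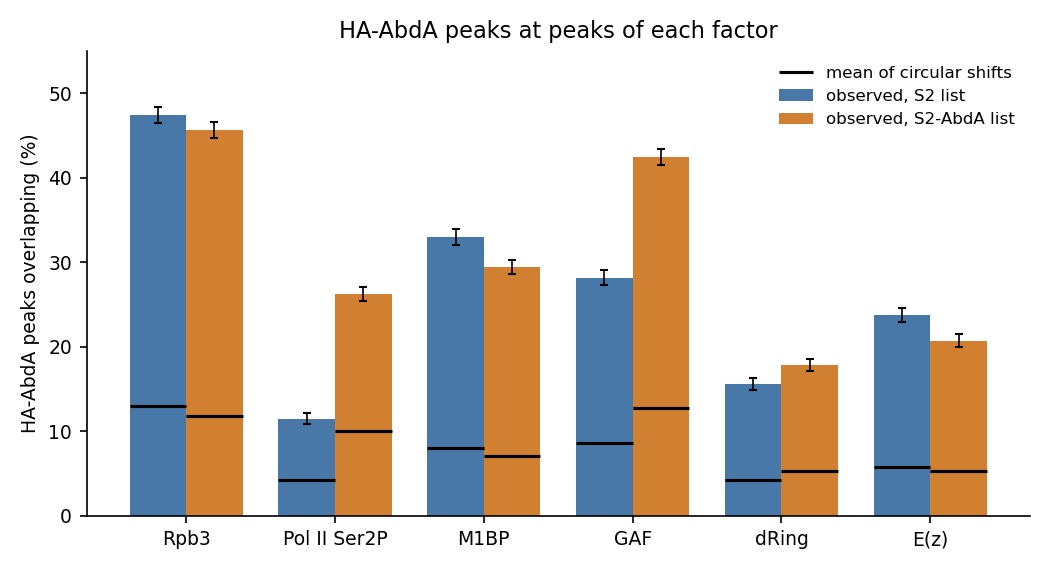
Share of the HA-AbdA peaks (percent, bars with exact 95% binomial intervals) that overlapped a peak of each factor in the S2 and in the S2-AbdA lists, with the mean over 1000 circular shifts as reference. Rpb3 had the largest shares, 47.4% and 45.6%, and every share lay above its shifted mean.

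Combining the lists of S2 cells, 34.0% of HA-AbdA peaks (3515) overlapped none of the 6 factors and 26.95% overlapped 3 or more. Rpb3 without Ser2P lay at 37.9% of HA-AbdA peaks and Rpb3 with Ser2P at 9.43%. With the lists of S2-AbdA cells, whose Ser2P list was longer, these shares were 24.7% and 20.9%. A Polycomb factor, dRing or E(z), lay at 28.2% of HA-AbdA peaks in S2 cells and at 29.0% in S2-AbdA cells, and both together lay at 11.1% and 9.52%.

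M1BP and GAF are both promoter-bound factors, and the design allows their share of AbdA sites to be compared. In S2 cells, 24.1% of HA-AbdA peaks (2496) overlapped M1BP without GAF, 19.3% (1995) overlapped GAF without M1BP, 8.87% (918) overlapped both and 47.7% (4943) overlapped neither. M1BP peaks without GAF carried HA-AbdA more often than GAF peaks without M1BP: 52.6% of 5096 (95% interval 51.2 to 54.0%) against 43.3% of 5087 (95% interval 41.9 to 44.6%), an odds ratio of 1.46. M1BP peaks that overlapped GAF carried HA-AbdA in 42.6% of 2061 cases, but on the arms in 62.3% of 1407 cases, against 61.8% for M1BP peaks without GAF there. In the S2-AbdA lists they carried it in 78.5% of 1362 cases. The difference passed the two-sided Fisher exact test over peaks (exact p = 4.1e-21) and 10000 circular shifts of the HA-AbdA label along the genome (two-sided permutation p = 0.0001, the smallest they can give). It did not hold in the lists of S2-AbdA cells, where the share was 39.2% of 5277 M1BP peaks without GAF and 53.1% of 8139 GAF peaks without M1BP, an odds ratio of 0.571 (permutation p = 0.013), and on the arms alone these were 54.9% and 53.3% (odds ratio 1.06, permutation p = 0.18).

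The comparison of the lines asked which factor peaks differed between cells without and with AbdA. M1BP, E(z) and Rpb3 occupied largely overlapping regions in both lines: 5875 M1BP regions had peaks in both (kept), 663 only in S2-AbdA cells (gained) and 1255 only in S2 cells (lost). For E(z) these counts were 5496, 945 and 1088, and for Rpb3 they were 7324, 1244 and 2018. The lists of GAF, dRing and Ser2P differed more. GAF had 4196 kept, 4904 gained and 2834 lost regions, of which 1648 lost regions lay outside the arms, so that the arms alone had 1186 lost ones. dRing had 3397 kept, 3059 gained and 1472 lost regions. Ser2P had 3899 kept, 2430 gained and 306 lost regions, of which 2075 gained and 56 lost regions lay on the arms. When both lists of a factor were limited to the length of the shorter one by score, Ser2P had 754 gained and 693 lost regions, and the gained regions numbered 2707 for GAF and 1680 for dRing. The covered bases shared by both lines, as a fraction of all covered bases (Jaccard index), were 0.74 for E(z), 0.68 for M1BP, 0.59 for Rpb3, 0.48 for dRing, 0.44 for Ser2P and 0.36 for GAF.

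Among Rpb3 regions, the highest-scoring gained peak lay at X 21893190 to 21893722 (score 266), and all 5 named gained peaks overlapped HA-AbdA. The 5 named lost Rpb3 peaks all lay on X, led by X 4581934 to 4582585 (score 289), and 4 of them overlapped HA-AbdA. The named gained Ser2P peak with the highest score lay at 3R 2666886 to 2667958 (score 119), away from HA-AbdA, whereas a wide one at 3L 13473335 to 13479415 (score 55.8) overlapped HA-AbdA, and the 5 named lost ones all lay in unplaced sequence. The leading gained M1BP peak lay at X 21210307 to 21211076 (score 327). On the arms the leading lost M1BP peaks lay at 3L 3471732 to 3472881 (score 367) and X 13739660 to 13740228 (score 367). GAF gained peaks at 2R 2107707 to 2109326 and 3L 12781457 to 12782298, both at the highest score of the list (401), and 4 of its 5 named gained peaks overlapped HA-AbdA. A lost GAF peak at 2L 347841 to 348573 (score 440) coincided with a gained dRing peak at 2L 347892 to 348501 (score 199), and 0 of the 5 named lost GAF peaks overlapped HA-AbdA. The others of these 5 lay in unplaced sequence, where HA-AbdA had few peaks. Of the 5 highest lost GAF peaks on the arms, 1 overlapped HA-AbdA. The leading lost dRing peak on the arms lay at X 4490217 to 4491803 (score 164) on HA-AbdA, and the leading lost E(z) peak lay at 3L 16838316 to 16838616 (score 31.4), also on HA-AbdA. Of the 5 named lost peaks, 1 overlapped HA-AbdA for dRing and 2 did for E(z), and 3 of the 5 highest on the arms did for each. A gained E(z) peak at 3R 10570388 to 10570892 (score 27.3) lay within the HA-AbdA peak at 3R 10569912 named among the 10 highest.

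These counts have no test, because 1 list per line gives no spread between replicates, and a peak can be absent from a list through depth or threshold. Lost peaks had lower scores than kept ones within each S2 list, with medians of 16.7 against 59.5 for Rpb3 and 13.8 against 39.7 for dRing. For GAF the gap was smaller, at 56.5 against 74.6 (70.4 against 74.7 on the arms). Outside the arms lost GAF peaks had the higher median, 50.4 against 40.9. Among the higher-scoring 50% of each list, compared with the whole list of the other line, gained and lost regions numbered 324 and 320 for Rpb3, 722 and 253 for dRing, 37 and 33 for E(z), 234 and 211 for M1BP, 255 and 85 for Ser2P and 1082 and 1287 for GAF.

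**Figure D3:**
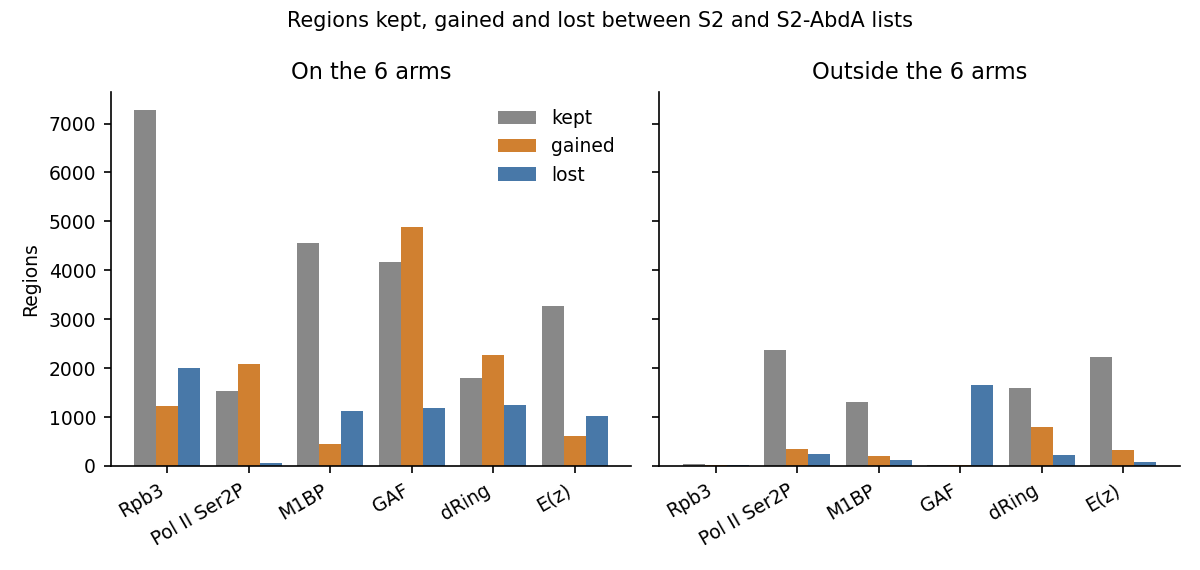
Number of regions (bars) of each factor with peaks in both lines (kept), in S2-AbdA cells only (gained) and in S2 cells only (lost), on the 6 arms (left) and outside them (right). GAF had the most gained regions on the arms, 4875, and of its lost regions 1186 lay on the arms and 1648 outside them.

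The last comparison between the lines asked whether regions that differed lay at AbdA-bound sites. At Polycomb regions, HA-AbdA was more frequent where a peak was lost. It lay at 60.9% of 1472 lost dRing regions and 24.6% of 3397 kept ones (odds ratio 4.77), and at 69.7% of 1088 lost E(z) regions and 35.7% of 5496 kept ones (odds ratio 4.13). The opposite held for Rpb3 and GAF: HA-AbdA lay at 52.5% of lost and 66.7% of kept Rpb3 regions (odds ratio 0.552), and at 15.1% of lost and 62.2% of kept GAF regions (odds ratio 0.108). Each of these 4 differences passed the test over 10000 circular shifts (two-sided permutation p = 0.0001, the smallest they can give, adjusted p = 0.00024). Only 40 HA-AbdA peaks lay outside the arms, whereas 1648 lost GAF, 1599 kept dRing and 2227 kept E(z) regions did. The odds ratios of GAF, dRing and E(z) over all chromosomes thus partly reflect where the regions lay. A kept region merges peaks of both lists, whereas a lost or gained one comes from 1 list. Kept regions can therefore be wider and touch HA-AbdA more readily. With peak centres within 250 bp, where peaks were not merged, the odds ratio was 0.646 at lost Rpb3 and 0.297 at lost GAF regions. In that setting it was 3.31 at lost dRing and 2.26 at lost E(z) regions.

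Gained GAF regions also carried HA-AbdA less often than kept ones, at 51.7% (odds ratio 0.651, adjusted permutation p = 0.00024). Gained dRing regions carried it in 40.6% of cases (odds ratio 2.10, adjusted permutation p = 0.0009) and gained E(z) regions in 43.5% (odds ratio 1.38, adjusted permutation p = 0.011). M1BP regions carried it in 48.6% of kept, 39.4% of gained and 55.5% of lost cases (adjusted permutation p = 0.0006 for gained and 0.034 for lost), and gained Rpb3 regions in 63.3% (adjusted permutation p = 0.028). At Ser2P, HA-AbdA lay at 46.7% of gained, 25.5% of kept and 9.15% of lost regions (odds ratio 2.57 for gained and 0.295 for lost). The difference at gained Ser2P regions did not pass (adjusted permutation p = 0.14), and that at lost regions did (adjusted permutation p = 0.00069). The result at gained Ser2P regions depended on the setting. A higher share than at kept regions passed with the higher-scoring 50% of each list (odds ratio 12.5), with lists of equal length (3.06), within score quintiles (1.43) and off Rpb3 (5.32). Each of these settings included regions outside the arms, where HA-AbdA had few peaks. There lay 2367 of 3899 kept and 355 of 2430 gained Ser2P regions. Within quintiles the label was permuted without regard to neighbouring regions, so that pass came from another test than the shifts. A lower share passed in regions on Rpb3 (0.549) and on the arms (0.663), and off Rpb3 on the arms the difference did not pass (1.14). The direction at lost Ser2P regions turned with peak centres within 250 bp (odds ratio 2.28) and with lists of equal length (odds ratio 1.15). Thus 11 of the 12 comparisons passed at 0.05 with shifts, and all 12 with the two-sided Fisher exact test over regions (largest adjusted exact p = 0.021), which treats neighbouring regions as independent.

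Several of these values moved on the arms alone, which held all but 0.386% of the HA-AbdA peaks. There HA-AbdA lay at 71.5% of lost and 46.3% of kept dRing regions (odds ratio 2.90). For E(z) regions the shares were 74.1% and 60.0% (odds ratio 1.91), and for GAF regions 35.9% and 62.5% (odds ratio 0.336). At gained Ser2P regions the direction turned on the arms, to 54.4% against 64.3% of kept ones (odds ratio 0.663), and at lost M1BP regions it turned to 61.3% against 62.2% (odds ratio 0.962). Some arm regions had peaks in at least 6 of the other lists rich in unplaced sequence (those with over 20% of peaks outside the arms). With these regions also left out, the share was 46.0% of lost and 60.8% of kept GAF regions (odds ratio 0.549) and 72.1% of lost and 64.0% of kept dRing regions. Gained dRing regions then stood below kept ones at 54.9% (odds ratio 0.684). Gained E(z) regions had 66.0% against 69.7% (odds ratio 0.845), which did not pass (adjusted permutation p = 0.088). Lost M1BP regions had 62.0% against 70.5% of kept ones (odds ratio 0.684, adjusted permutation p = 0.0002), a reversal that passed. Within quintiles of the peak score, the odds ratio turned to 0.622 at gained E(z) regions and to 1.05 at gained Rpb3 regions, and on the arms it was 1.02 at lost E(z) regions. With peak centres within 250 bp it turned to 0.877 at gained E(z) and 0.805 at lost M1BP regions. With the higher-scoring 50% of each list, the odds ratio at lost Rpb3 regions was 0.994, and within regions on Rpb3 the one at lost GAF regions was 0.887.

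**Figure D4:**
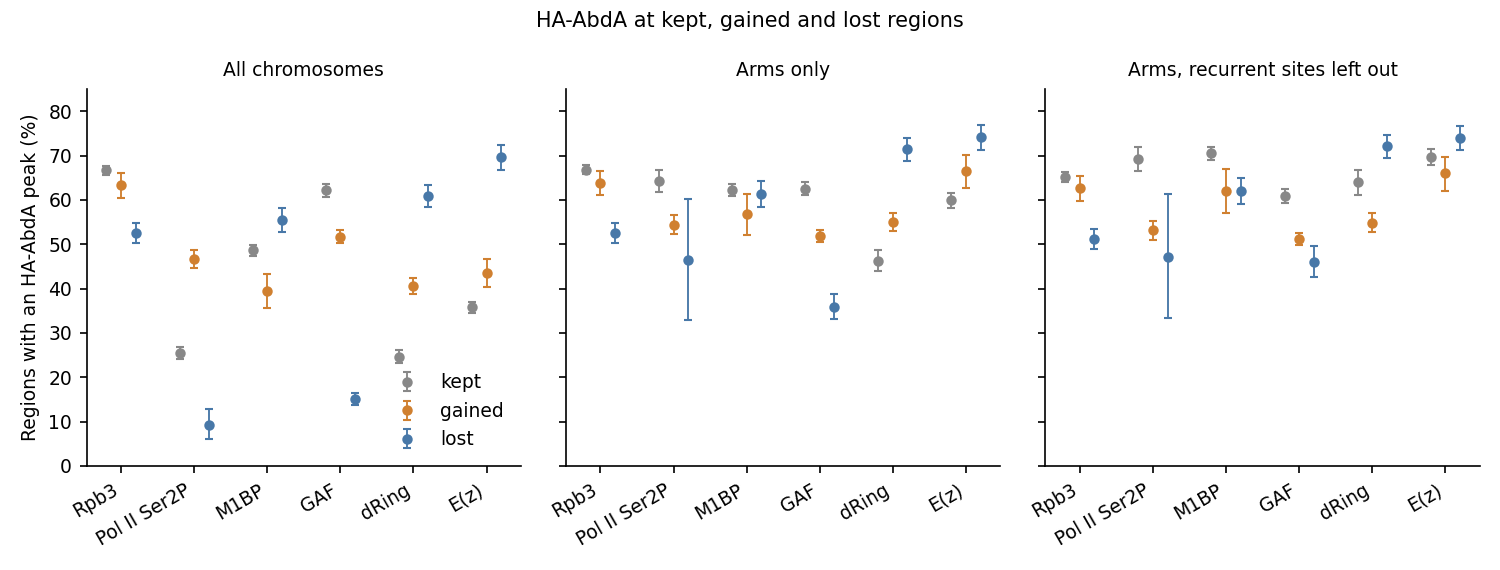
Share of the kept, gained and lost regions of each factor (percent, points with exact 95% binomial intervals) that overlapped an HA-AbdA peak, over all chromosomes, on the arms, and on the arms without sites that recur in the lists rich in unplaced sequence. Lost dRing regions lay above kept ones in every panel, from 60.9% against 24.6% to 72.1% against 64.0%, and lost Rpb3 and GAF regions lay below kept ones.

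The overlaps of the factors with each other were also counted in each line. dRing and E(z), of the 2 Polycomb complexes, had the largest overlap relative to shifts: 75.6% of dRing peaks lay on E(z) in S2 cells (16.2 times the shifted mean) and 60.2% in S2-AbdA cells (14.2 times), and 54.5% and 57.4% of E(z) peaks lay on dRing. Rpb3 peaks overlapped Ser2P in 16.0% of cases in S2 cells and 40.5% in S2-AbdA cells, 4.26 and 4.58 times the shifted means of 3.76% and 8.84%. Rpb3 peaks overlapped M1BP in 41.6% and 38.1% of cases and GAF in 31.4% and 48.1%. M1BP peaks lay on GAF in 28.8% of cases in S2 cells and 20.5% in S2-AbdA cells, but on the arms alone in 24.6% and 26.5%. dRing peaks lay on M1BP in 55.6% and 42.4% of cases, and E(z) peaks lay on Rpb3 in 34.6% and 30.7% (52.8% and 50.3% on the arms). On Ser2P lay 60.0% and 65.7% of dRing peaks (38.5% and 51.3% on the arms). For E(z) peaks on Ser2P the shares were 56.4% and 66.3% (38.5% and 52.8% on the arms). All 60 ordered pairs overlapped more than in any of 1000 circular shifts (one-sided permutation p = 0.001 and adjusted p = 0.001 for each, the smallest these shifts can give). The differences between the lines were not tested. No pair was run without recurrent sites, so sites common to the lists rich in unplaced sequence cannot be told apart from shared chromatin.

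**Figure D5:**
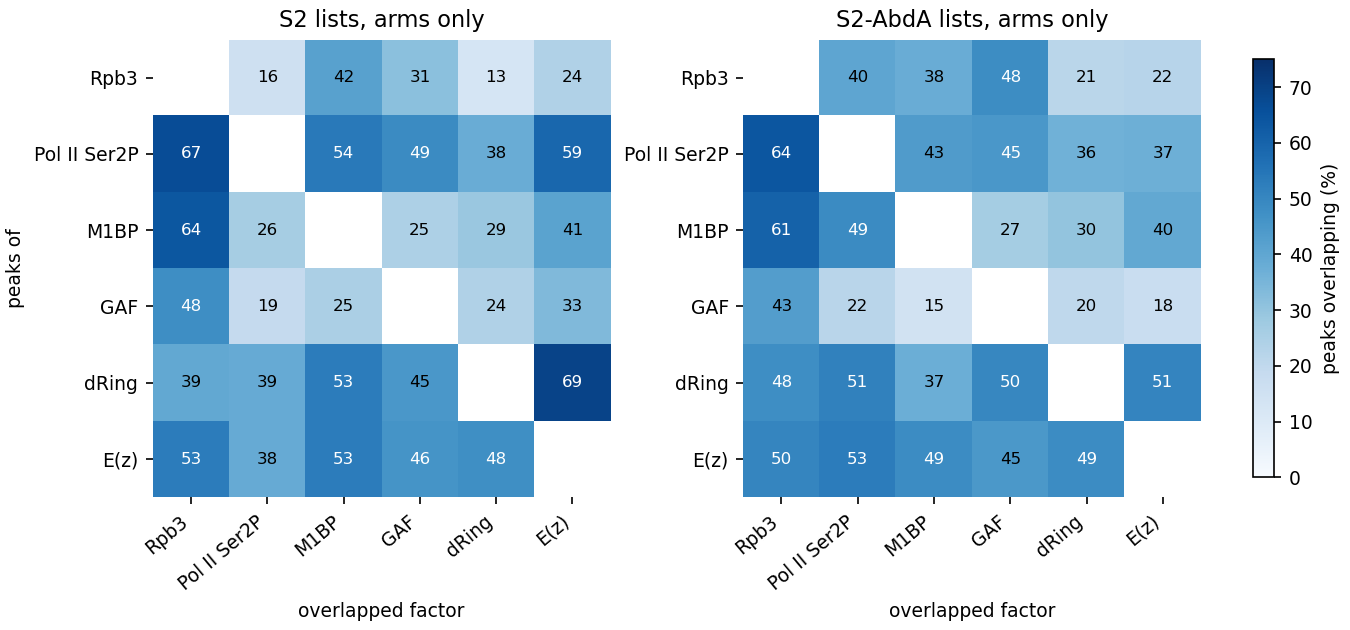
Share of the peaks of each factor on the arms (vertical axis, percent as a colour scale and printed in each cell) that overlapped a peak of each other factor (horizontal axis), in S2 and in S2-AbdA cells. The highest share was that of dRing peaks on E(z) in S2 cells, 69.4% on the arms.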

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

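The tests of the input code, of AbdA binding at gained GAF and of recurrent sites as the whole difference at lost dRing and E(z) regions were chosen only after the result was seen, as were the settings on the arms for these comparisons and without recurrent sites.

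M1BP peaks without GAF carried HA-AbdA more often than GAF peaks without M1BP in the S2 lists (odds ratio 1.46) and less often in the S2-AbdA lists (odds ratio 0.571). This stood out because the lines gave opposite directions under 1 contrast, and the difference between the lines itself was not tested. On the arms the odds ratio was 1.37 in the S2 lists and 1.06 in the S2-AbdA lists (permutation p = 0.18). In the S2-AbdA lists, M1BP peaks without GAF numbered 5277 over all chromosomes and 3752 on the arms, of which 2070 and 2058 carried HA-AbdA. GAF peaks without M1BP numbered 8139 and 8088. The value under 1 thus rested on M1BP peaks outside the arms, where HA-AbdA had few peaks.

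Of the 13 lists, 9 had over 20% of their peaks outside the arms and 4 had 0.629% or less. Input control as the only cause is argued against, because lists of 1 input code differed by up to 60.6 percentage points in this share. A candidate explanation is a class of repeat-like sites that were left out of the 4 lists: arm regions with a peak in all 9 of the former lists lay on S2 Rpb3 peaks in 41.0% of 266 cases, against 74.1% of 1957 regions with a peak in 5 to 8 of them, a difference of -33.2 percentage points. A low share on Rpb3 is not particular to such regions, since those with a peak in 1 of the lists had 31.7% (of 4182), so it does not by itself mark repeats. Whether such sites were filtered from some lists is not given in the sources used here, and no biological explanation was tested.

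The GAF lists of the lines had a Jaccard index of 0.36 (0.395 on the arms, where that of Ser2P was 0.344). On the arms, recurrent sites made up 31.1% of lost and 7.70% of kept GAF regions, 23.4 percentage points more (permutation p = 0.0001, the smallest these shifts can give), so a part of the losses may come from repeat-like sites that the S2-AbdA list lacks, although HA-AbdA lay at 13.6% of the recurrent lost and 82.6% of the recurrent kept regions and these sites are thus a mixed class. AbdA binding as a source of gained GAF is undecided: at Rpb3 regions kept on the arms the odds ratio between HA-AbdA and a GAF peak new in S2-AbdA cells was 1.75, but that with GAF in S2 cells, which lack AbdA, was already 1.59, a ratio of 1.10 (95% block bootstrap interval 0.914 to 1.30). The line and the input code cannot be told apart for GAF (B in S2 cells, C in S2-AbdA cells), nor for the other 5 factors (B and D), dRing and E(z) included. Which of these accounts for the gained GAF regions stays open.

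HA-AbdA was more frequent at lost than at kept Polycomb regions on the arms, by 25.1 percentage points for dRing and 14.2 for E(z). Without recurrent sites the differences were 8.11 (permutation p = 0.0004) and 4.31 percentage points (permutation p = 0.011), so recurrent kept regions may account for the larger part of both, but not for the whole, since odds ratios of 1.45 and 1.24 remained. These sites are a mixed class and not shown to be repeats, as HA-AbdA lay at 15.4% of recurrent kept and 65.3% of recurrent lost dRing regions, and at 21.3% and 80.0% of E(z) ones. Weak peaks are argued against for dRing, where the odds ratio within score quintiles on the arms was 2.42 (permutation p = 0.0001), and may account for E(z), where it was 1.02 (permutation p = 0.79), and transcribed chromatin cannot be told apart from AbdA for either factor: within regions on Rpb3 the difference was 5.47 percentage points for dRing (permutation p = 0.019) and -1.34 for E(z) (permutation p = 0.47), against 33.0 and 30.1 off Rpb3. Loss of dRing at AbdA-bound sites remains a hypothesis from these data (odds ratio 1.72 within score quintiles without recurrent sites), because it was found and tested on the same lists and has no replicates.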

How the results depend on the processing

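The settings on the arms (except for the HA-AbdA list and its overlaps) and without recurrent sites were chosen only after the result was seen. No paired analysis was possible because 1 pooled list per antibody and line carries no replicates, and for the same reason no replicate could be left out. Promoters bound, gene lists and sequence motifs were not run, with their alternatives, because no dm3 annotation or genome was used here. All 240 alternatives of factor pairs and 56 of 58 of the HA-AbdA overlaps kept their direction and side of the threshold. None of these left out recurrent sites. Of 84 gained or lost counts 50 stayed within 1.5 times. Of 148 alternatives for HA-AbdA at gained or lost regions 94 kept direction and side, 33 reversed and 17 kept direction but no longer passed. The 33 were counted by direction alone, whether or not they passed. Not passing were, for example, 1.09 at gained Rpb3 (higher-scoring 50%) and 0.962 at lost M1BP (arms). Another 4 newly passed in the main direction, all at gained Ser2P (12.5, 3.06, 1.43 and 5.32). At gained Ser2P, reversed alternatives passed as well: 0.549 on Rpb3, 0.663 on the arms and 0.502 there without recurrent sites. Others that passed were 0.506 on Rpb3 on the arms, and within score quintiles 0.636 on the arms and 0.601 there without recurrent sites. Settings with score quintiles, such as that at 1.43, were judged by permutation within quintiles, which treats neighbouring regions as independent. The main setting was judged by circular shifts, so passes under the 2 are not alike. HA-AbdA was more frequent at lost dRing regions and less frequent at lost Rpb3, lost GAF and gained GAF regions in every alternative run, all past the threshold except those at 0.994, 0.887, 0.9505 and 0.892. For the values that changed, the cause was not tested, except that shorter lists hold fewer peaks. Read depth is unknown, so a peak missing from a list can be a matter of depth.

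With the higher-scoring 50% of each list, the HA-AbdA list held 5176 peaks, and 1.60% overlapped S2 Ser2P. Gained regions were 781 for Rpb3, 1261 for Ser2P, 2434 for GAF, 1314 for dRing and 457 for E(z), and lost ones 1086 for Rpb3, 1402 for GAF, 518 for dRing and 540 for E(z). The odds ratio of HA-AbdA was 1.09 at gained and 0.994 at lost Rpb3 regions, and 12.5 at gained and 0.207 at lost Ser2P regions. M1BP against GAF gave 1.31 in the S2 lists with this score cut. Without the score cut, it gave 0.571 in the S2-AbdA lists and 1.06 there on the arms. Also without the cut, the odds ratio for Ser2P within Rpb3 peaks of S2-AbdA cells was 1.07.

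With centres within 250 bp, gained Rpb3 regions were 2161 and lost Ser2P regions 1453, and the odds ratio was 2.28 at lost Ser2P, 0.805 at lost M1BP, 1.09 at gained dRing and 0.877 at gained E(z). Among strong peaks, gained and lost regions were 324 and 320 for Rpb3, 255 and 85 for Ser2P, 234 and 211 for M1BP, 1082 and 1287 for GAF, 722 and 253 for dRing, and 37 and 33 for E(z). With equal list lengths, Ser2P had 754 gained and 693 lost regions, GAF 2707 gained and dRing 1680 gained, and the odds ratio was 3.06 at gained and 1.15 at lost Ser2P. With an overlap of 50% of the shorter peak it was 0.903 at gained Rpb3.

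On the arms, lost regions were 56 for Ser2P and 1186 for GAF, and gained E(z) regions 617, with odds ratios of 0.663 at gained Ser2P and 0.962 at lost M1BP. Without recurrent sites, lost regions were 53 for Ser2P and 817 for GAF, gained ones 387 for M1BP and 606 for E(z), and the odds ratios were 0.898 at gained Rpb3, 0.502 at gained Ser2P, 0.684 at lost M1BP, 0.684 at gained dRing and 0.845 at gained E(z).

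Within score quintiles, the odds ratio was 1.05 at gained Rpb3, 1.43 at gained Ser2P and 0.622 at gained E(z). On the arms these were 1.07, 0.636 and 0.6996, with 1.17 at gained dRing and 1.02 at lost E(z). Without recurrent sites they were 1.07, 0.601 and 0.692, with 0.955 at lost M1BP, 0.892 at gained GAF, 0.729 at gained dRing and 1.02 at lost E(z).

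In regions on Rpb3, it was 0.549 at gained and 0.666 at lost Ser2P, 0.832 at gained and 0.869 at lost M1BP, 0.887 at lost GAF, 0.704 at gained dRing, and 0.909 at gained and 0.979 at lost E(z). On the arms these were, in the same order, 0.506, 0.701, 0.840, 0.863, 0.9505, 0.641, 0.884 and 0.921. Off Rpb3 it was 5.32 at gained Ser2P, 1.10 at lost Ser2P and 1.30 at gained E(z), and on the arms 1.14 at gained Ser2P (not passing), 1.21 at lost Ser2P and 0.786 at gained M1BP.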

Other observations

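The comparison across HA-AbdA score quintiles and the tests of new Ser2P peaks at Rpb3 regions were chosen only after the result was seen.

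Higher-scoring HA-AbdA peaks on the arms lay more often on every factor named here. From the lowest to the highest score quintile (2063 peaks each), the share on S2 Rpb3 peaks was 25.4% and 65.1%, on S2 M1BP peaks 13.1% and 48.3%, on S2 GAF peaks 16.8% and 41.3%, on S2 dRing peaks 5.28% and 31.8% and on S2 E(z) peaks 7.51% and 45.4%. Peaks of the highest quintile were wider (median 1180 bp against 610 bp), and with peak centres within 250 bp in place of overlap the shares were 3.49% and 20.9% for dRing and 5.28% and 29.2% for E(z).

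Ser2P peaks appeared in S2-AbdA cells at 30.1% of 6009 Rpb3 regions on the arms that were kept in both lines and had no Ser2P peak in S2 cells. The share was 30.5% of 3940 regions with HA-AbdA and 29.2% of 2069 without it, and 31.6% of 2713 regions with M1BP of S2 cells and 28.8% of 3296 without it. Split by both, it was 32.7% of 1939 regions with HA-AbdA and M1BP, 28.3% of 2001 with HA-AbdA alone, 28.7% of 774 with M1BP alone and 29.6% of 1295 with neither. The hypothesis that AbdA or M1BP goes with gained Ser2P was tested against the association already present in S2 cells. The odds ratio between HA-AbdA and new Ser2P was 1.06, against 1.40 with Ser2P in S2 cells, a ratio of 0.756 (95% block bootstrap interval 0.620 to 0.909). For M1BP these were 1.14 and 1.16, a ratio of 0.984 (95% block bootstrap interval 0.824 to 1.16). For HA-AbdA the interval of the ratio lay below 1, so new Ser2P peaks of these regions showed no excess over the association in S2 cells. This does not decide on AbdA, because the Ser2P list of S2-AbdA cells was longer and a new peak can be a matter of depth. A weak association is not excluded, since the 95% interval of the odds ratio of 1.06 ran from 0.932 to 1.21. For M1BP the interval of the ratio held 1, and that hypothesis stays undecided. GAF gave 27.3% with and 31.5% without, which was not tested.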
